A study of Mus musculus with 8 samples.

How the data were processed

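RNA from dendritic cells sorted from mouse thymus was hybridised to 8 Agilent arrays of 1 colour (Cy3), which lay on 1 slide in 2 rows. Per the labels, the cells were sorted by Sirpa, an inhibitory surface receptor that marks a subset of dendritic cells, and by maturation status, which gave 4 groups with 2 arrays each. The labels name no other sort marker, and they do not say whether the arrays of a group came from separate mice or separate sorts. The p-values therefore measure only the spread between these samples, which may be technical.

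The scanner files hold spot intensities, per the file headers the output of Feature Extraction 10.7.3.1 with its background subtraction and spatial detrending (the processed signal), and the medians of the spot and local background pixels. The submitters' processing notes give version 10.5 of that program instead, and the difference was not resolved. The authors' deposited value table holds log2 values, and the deposited values themselves show quantile normalization, since the 8 sorted columns differ by at most 0.095. Within each array the ranks of that table follow the median pixel signal without background subtraction (rank correlation 1). The submitters' processing notes name limma for the authors' values, without a version, and its settings are not given in the sources used here. The table's medians per array lie between 5.99 and 6.01. Its scale was inferred as log2 from its range, its direction follows the signal, and no centring of genes was seen.

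The 59305 spots that are not controls carry 55681 probes. Spots that the scanner software marked as non-uniform or population outliers, 110 to 270 per array, were set missing, and spots of the same probe were averaged. Of the probes kept in the filter below, 62 were left without a value on at least 1 array. The log2 of the processed signal minus the array's 75th percentile of it was the measurement. A probe was kept where it was well above background on both arrays of at least 1 group, which left 33686 probes. Probe accessions were named through a RefSeq table of assembly GRCm38.p6, matched without version numbers; 26582 probes received a symbol and 29099 kept the accession or probe name. The array design's header names mm9, so no coordinates are printed. For 5871 genes with several kept probes, the probe with the highest mean over the 8 arrays stood for the gene, which left 24145 genes or accessions, 13865 of them with a symbol.

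All 8 arrays entered a single limma model (limma 3.58.1, R 4.3.3) with 4 group means, moderated variances and 4 residual degrees of freedom (3.26 prior). From it came the 2 maturation comparisons, the 2 subset comparisons, the difference between the maturation effects and, as counts only, the 2 remaining pairs of groups. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05 on the adjusted p. Values are log2 differences with their standard errors (SE). Where a probe was not well above background on either array of the dimmer group, its fold is a lower bound, "at least N-fold". It sets the brighter group's mean against the mean, over the dimmer group's arrays, of the higher of the probe's own signal and the lowest signal of any probe well above background on that array.

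Before the data were examined, 31 gene lists with 827 entries were fixed, of which 809 were on the array and 18 were not matched and are not analysed here. Each list was tested with limma's camera at a preset correlation between genes of 0.01 and again with the correlation estimated per list, adjusted over the 155 tests of 31 lists in 5 comparisons. Of these, 85 passed at the preset correlation and none (0) with the estimated one. The comparisons, the alternatives and the rule for naming genes were fixed at the same time. The rule took, per comparison, the 8 largest rises and 8 largest falls among genes with a full symbol that passed the test, did not overlap between the groups and were well above background on both arrays of the higher group. It added up to 2 risen and 2 fallen members per described list, those with the smallest p, and Cd40, Sirpa, Ccr7, Cd80, Cd86, Xcr1, Irf8 and Irf4 throughout.

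The model was tested on simulated data built for the Sirpa-positive maturation comparison over 24101 genes. Of 50 genes changed by 0.5 on the log2 scale it recovered 0%, of 50 changed by 1 it recovered 2%, of 50 changed by 2 it recovered 54% and of 50 changed by 3 it recovered 84%, with 4 false calls in that comparison and 0 in an unchanged comparison. The number of arrays limits the precision. The simulation changed only 200 genes, and with more changed genes the adjusted p reaches smaller changes.

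Alternatives covered normexp background correction (offset 50) with quantile normalization, quantile and median scaling, the authors' values, other filters on dim probes, all probes tested singly, the slide row or the set of title numbers as a block, trended and robust variances, array weights, fits on the compared arrays alone, a 2-fold minimum and leaving out each array. The scanner files used here give no mean pixel signal, so normexp was run on the median pixel signal. The mean of a gene's kept probes was an alternative added after seeing the data. Dendritic cells of the subset lists express many genes of the other lists, and the number of members shared with other lists differs from list to list. Families of close relatives, such as the kallikreins related to Klk1 and the Cd209 genes, can cross-hybridise, so their values are uncertain for single members.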

Results

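Dendritic cells of the mouse thymus were compared between 2 subsets, with and without surface Sirpa, and between 2 maturation states, in a study of CD40 in the maturation of these cells and in the development of regulatory T cells. CD40 is a receptor on antigen-presenting cells that T cells engage. Each of the 4 groups had 2 arrays, named here by the number in their title: replicates 1 and 6 (Sirpa-positive mature), 3 and 5 (Sirpa-positive immature), 2 and 8 (Sirpa-negative mature) and 4 and 7 (Sirpa-negative immature). The 75th percentile of the processed signal ranged from 147 to 313 intensity units between arrays. Between 52.9% and 65.5% of spots were well above background, with 61.9% to 65.5% in the first row of the slide and 52.9% to 57.9% in the second row, and no spot (0) was saturated. Each row held 1 array of every group.

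Arrays of the same group correlated at 0.979 to 0.987 across genes, and arrays of different groups at 0.908 to 0.963. The first principal component held 42.2% of the variance and separated the subsets, and the second component held 34.3% and separated the maturation states. The sorting marker itself followed the labels. Sirpa stood 6.83 ± 0.224 (log2, SE, n = 2 arrays per group) higher in Sirpa-positive than in Sirpa-negative immature cells, a 114-fold difference, and 28.3-fold higher among mature cells. Ccr7, the chemokine receptor that guides mature dendritic cells, was 71.7-fold and 51.5-fold higher in the mature cells of the Sirpa-positive and Sirpa-negative subsets. The named genes counted here and over the alternatives below are the leading rises and falls and the genes fixed beforehand. Members named only from a list are not among them. These genes gave 81 results that passed, counting a gene once per comparison, and 81 had the same direction within each row of the slide. For genes picked by their rise or fall this was fixed in advance, because the rule required groups that do not overlap. The medians in 80 of the 85 list tests that passed, counted in the same way, had the same direction in both rows too. The exceptions were cytokines and the actin list in Sirpa-positive maturation, the MHC class II pathway in both subset comparisons and the plasmacytoid markers among immature cells.

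**Figure D1:**
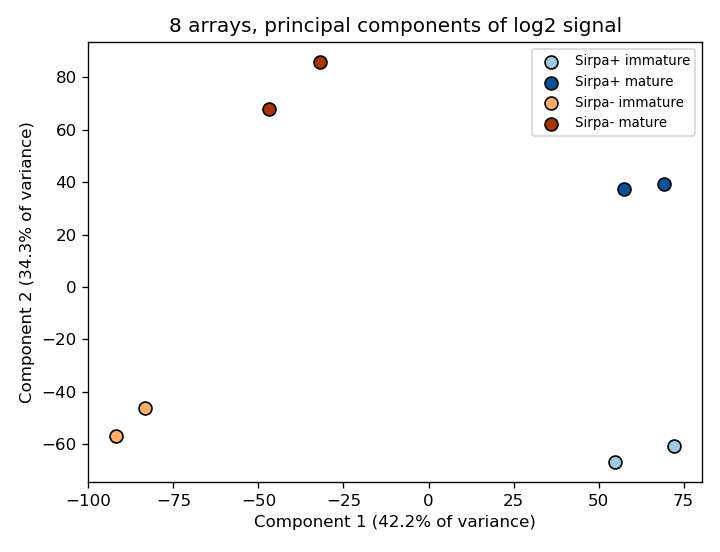
Each point is 1 array, placed by its first principal component (x, 42.2% of the variance) and its second (y, 34.3%) of log2 signal, in arbitrary units, and coloured by group. Both arrays of every group lie close together, with Sirpa-positive cells at the right, Sirpa-negative cells at the left and mature cells above immature cells.

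The first comparison asked what maturation changed in Sirpa-positive cells. Ccr7 rose by 6.16 ± 0.597 on the log2 scale (SE, n = 2 arrays per group, adjusted p = 0.00255). Ccl22, a chemokine that attracts cells carrying Ccr4, rose 42.3-fold, and Arc, best known as an activity-induced gene of neurons, rose 56.8-fold. Cd40 rose 4.46-fold (2.16 ± 0.314, adjusted p = 0.0103) and Cd80, a ligand of CD28, 2.60-fold (1.38 ± 0.231, adjusted p = 0.0165). Cd86 stood 0.76 ± 0.215 higher (adjusted p = 0.0906) and Sirpa -0.50 ± 0.224 lower on the log2 scale (adjusted p = 0.272), and neither passed. Nor did Xcr1, at least 1.38-fold lower and not above background on the mature arrays (adjusted p = 0.166), Irf8 (0.94 ± 0.246, adjusted p = 0.0716) or Irf4 (0.27 ± 0.248, adjusted p = 0.628).

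Among the other leading risers in Sirpa-positive cells were Ceacam15 (67.5-fold, measured on 1 of the 2 immature arrays), Dscaml1 (43.5-fold), Apol7c (43.1-fold), Apol7a (41.0-fold) and the serine protease inhibitor gene Serpinb6b (42.7-fold). The largest falls were in lectin receptors of the Cd209 family, related to the human pathogen receptor DC-SIGN. Cd209a fell 23.1-fold (-4.53 ± 0.242 on the log2 scale), Cd209e 12.9-fold, Cd209d 12.2-fold and Cd209c at least 9.91-fold. These relatives can cross-hybridise, so the single values are uncertain. Rbp4, a retinol carrier, fell 12.8-fold, with 1 of 2 mature arrays above background, the water and glycerol channel Aqp3 10.3-fold, the galactose-binding lectin Clec10a 10-fold and Cyp2s1 at least 4.22-fold.

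The fixed lists for maturation moved with these genes in Sirpa-positive cells. Of 35 tested genes of dendritic cell maturation and migration, 28 rose, 0 fell and 7 did not pass, and 31 rose when adjusted over the list alone (camera adjusted p = 1.9e-27, and adjusted p = 0.161 with an estimated correlation). Serpinb6b and the costimulatory receptor gene Tnfrsf4 (21.7-fold) had the smallest p. CD40 and NF-kB signalling had 13 risen and 0 fallen of 29 (20 risen adjusted over the list alone; adjusted p = 5.99e-11, and adjusted p = 0.118 with an estimated correlation), led by Birc2 (6.77-fold) and the NF-kB subunit Relb (5.92-fold). Costimulatory and coinhibitory ligands had 8 risen and 2 fallen of 20, with 11 risen and 4 fallen adjusted over the list alone (adjusted p = 0.00721, and adjusted p = 0.445 with an estimated correlation). Cd70, the ligand of CD27, rose 31.6-fold (1 of 2 immature arrays above background) and Cd200 12.2-fold. Vsir fell 1.99-fold and Tnfsf14 4.31-fold (1 of 2 mature arrays). Of 29 mediators that support regulatory T cells, 12 rose and 0 fell, with 16 risen and 3 fallen adjusted over the list alone (adjusted p = 4.5e-06, and adjusted p = 0.223 with an estimated correlation). This list shares 15 of its tested members with other lists. Besides Cd70 it was led by Aldh1a2, an enzyme of retinoic acid synthesis (8.96-fold).

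Further lists in Sirpa-positive cells went both ways. The cytokine and chemokine list had 5 risen and 1 fallen of 26 (8 and 2 adjusted over the list alone), with Ccl5 up 17.1-fold and Il15 up 7.24-fold and Ccl6 down 1.95-fold (adjusted p = 0.0241, and adjusted p = 0.491 with an estimated correlation). Cell cycle genes had 17 fallen and 0 risen of 37, 31 fallen adjusted over the list alone. Among them were the kinesin gene Cenpe (2.71-fold) and Cdc20 (2.73-fold), with camera adjusted p = 7.28e-19 and adjusted p = 0.198 with an estimated correlation. Type 2 dendritic cell markers had 6 fallen and 1 risen of 30 (12 and 1 adjusted over the list alone), with the transcription factor gene Klf4 down 3.81-fold and Esam up 4.93-fold (adjusted p = 6.8e-05, and adjusted p = 0.129 with an estimated correlation). In the MHC class I list 4 of 21 rose and 0 fell, 6 adjusted over the list alone, led by the lipid-presenting molecule Cd1d1 (10-fold) and Tapbpl (3.87-fold; adjusted p = 5.67e-05, and adjusted p = 0.198 with an estimated correlation). The MHC class II list did not pass (adjusted p = 0.738), with 1 riser of 18, H2-Eb2 (9.23-fold). In cholesterol synthesis, 4 of 26 rose and 0 fell, 11 adjusted over the list alone, with Idi1 at 7.54-fold (adjusted p = 0.000203, and adjusted p = 0.362 with an estimated correlation). Beside these changes, 10 of 26 thymocyte and T cell markers were higher in the mature samples and 0 lower, 17 and 0 adjusted over the list alone. They were led by Tcf7 (5.90-fold) and Thy1 (2.27-fold; adjusted p = 8.06e-09, and adjusted p = 0.0868 with an estimated correlation). Of 28 macrophage and monocyte markers, Marco (2.99-fold) and Mrc1 (4.79-fold) were lower, 0 were higher and 6 were lower adjusted over the list alone (adjusted p = 1.89e-05, and adjusted p = 0.34 with an estimated correlation).

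Of 24145 genes tested in Sirpa-positive cells, 1050 rose and 612 fell with maturation (1662 in all, 63.2% of them rises), 987 and 521 of them by at least 2-fold. Leaving out an array gave 907 without mature replicate 1, 390 without mature replicate 6, 415 without immature replicate 3, 449 without immature replicate 5. The total was 1061 with the slide row as a block and 430 with dim probes kept, and the share of rises was 50.9% of calls with normexp and quantile normalization together and 59.6% with quantile normalization alone. Cd40 missed the threshold without mature replicate 1 (adjusted p = 0.0522), without mature replicate 6 (adjusted p = 0.0594), without immature replicate 5 (adjusted p = 0.0793) and with dim probes kept (adjusted p = 0.054). Its adjusted p ranged from 0.000502 to 0.0793 over 22 alternatives, of which 18 passed, and its log2 change stayed between 1.95 and 2.37. Cd80 passed in 16 of 22 (adjusted p from 0.00156 to 0.25), and it missed without mature replicate 1 (0.0542) or 6 (0.0973), without immature replicate 3 (0.114) or 5 (0.0924), with dim probes kept (0.0792) and as the mean of its probes, where its log2 change was 0.41. Ceacam15 missed without mature replicate 1 (0.107) or 6 (0.13), with dim probes kept (0.109) and from the compared arrays alone (0.0611) (range 0.000189 to 0.13). Rbp4 missed without mature replicate 6 (0.0569) or immature replicate 3 (0.0778) and with dim probes kept (0.0581) (range 0.000856 to 0.0778). Clec10a missed without immature replicate 3 (0.0544) or 5 (0.0839) and with dim probes kept (0.0566) (range 0.000525 to 0.0839) and Ccl22 without mature replicate 6 (0.0531) (range 5.78e-05 to 0.0531). Large folds varied with the processing and the arrays used. Over the alternatives the log2 rise lay between 3.11 and 8.21 for Ceacam15, 3.38 and 6.07 for Dscaml1 and 5.45 and 6.66 for Ccr7. Irf8 passed in 5 of 22 alternatives, without mature replicate 1 (log2 change 1.25), with normexp and quantile normalization (adjusted p = 0.0112), the authors' values (0.027), probes above background on all 8 arrays (0.0391) and trended and robust variances (0.0234). Its change was under the 2-fold minimum. Cd86 passed in 3 of 22, with normexp and quantile normalization (0.0167), the authors' values (0.0297) and trended and robust variances (0.0296), and its change was under the 2-fold minimum as well.

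**Figure D2:**
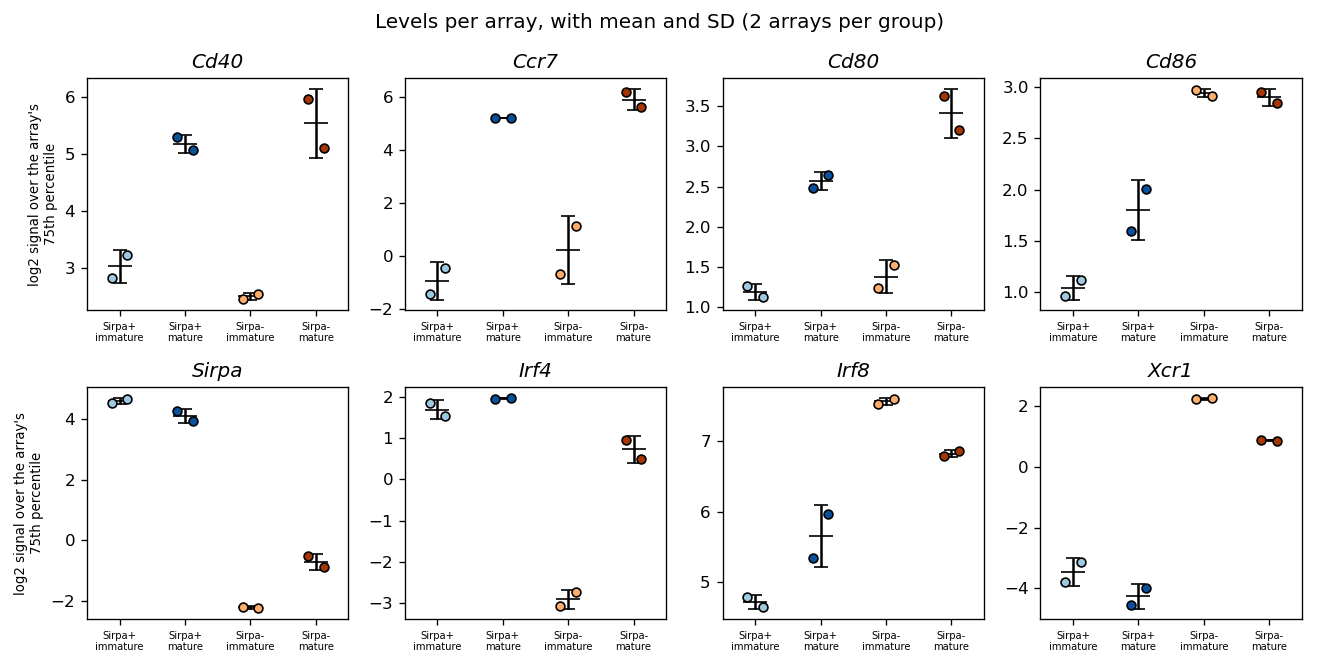
Log2 signal over the array's 75th percentile (y) of 8 genes fixed beforehand in the 4 groups (x); points are the 2 arrays of a group, with the group's mean and SD as bars, and each panel has its own y range. Cd40 and Ccr7 stand higher on every mature array than on any immature array.

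The same comparison in Sirpa-negative cells followed 2 arrays per state. Cd40 rose 8.22-fold (3.04 ± 0.314 on the log2 scale, SE, n = 2 arrays per group, adjusted p = 0.00148), Ccr7 51.5-fold and Cd80 4.11-fold (2.04 ± 0.231, adjusted p = 0.00201). Irf4, a transcription factor of type 2 dendritic cells, rose 12.3-fold (3.63 ± 0.248, adjusted p = 0.000513), and Sirpa itself rose 2.85-fold (1.51 ± 0.224, adjusted p = 0.00555). Xcr1, the chemokine receptor of type 1 dendritic cells, fell 2.59-fold (-1.38 ± 0.290 on the log2 scale, adjusted p = 0.0198). Cd86 changed by -0.04 ± 0.215 and Irf8 by -0.74 ± 0.246, and neither passed (adjusted p = 0.923 and adjusted p = 0.0859).

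Gng4, a G protein subunit gene measured on 1 of the 2 immature arrays, led the risers in Sirpa-negative cells at 146-fold. It was followed by Ccl22 (98.1-fold), Insl6 (65.4-fold), the Notch ligand Jag1 (63.8-fold, 1 of 2 immature arrays), and 4 genes not well above background before maturation: the transcription factor gene Stat4 (at least 56.4-fold), Insm1 (at least 56.4-fold), Thbs4 (at least 50-fold) and Flrt3 (at least 26.6-fold). Genes of tissue kallikreins, a family of serine proteases, made up 5 of the 8 largest falls, namely Klk1 (22.0-fold), Klk1b5 (20.2-fold), Klk1b24 (18.1-fold), Klk1b26 (13.6-fold) and Klk1b4 (12.5-fold). Their sequences are close enough to cross-hybridise, so they need not be separate events. Tlr3, a sensor of double-stranded RNA, fell 11.9-fold, Lmo1 at least 9.36-fold and Cd209a at least 4.89-fold.

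Maturation genes led the list changes here as well, with 31 of 35 risen and 0 fallen, and 31 risen adjusted over the list alone (camera adjusted p = 1.14e-22, and adjusted p = 0.181 with an estimated correlation). Tnfrsf4 rose 26.6-fold and Relb 9.28-fold. In CD40 and NF-kB signalling 23 of 29 rose and 0 fell, 25 adjusted over the list alone, with Birc2 at 7.93-fold (adjusted p = 7.23e-15, and adjusted p = 0.0904 with an estimated correlation). Costimulatory and coinhibitory ligands had 12 risen and 1 fallen of 20, as they did adjusted over the list alone. They included Cd70 (50.5-fold, 1 of 2 immature arrays above background), the PD-L1 gene Cd274 (31.9-fold) and, falling, Vsir (2.27-fold; adjusted p = 1.69e-05, and adjusted p = 0.248 with an estimated correlation). Mediators that support regulatory T cells had 19 risen and 1 fallen of 29, again also adjusted over the list alone, and the 1 that fell was Tgfb1 (2.41-fold; adjusted p = 1.3e-08, and adjusted p = 0.181 with an estimated correlation). Cytokines and chemokines had 15 risen and 1 fallen of 26, 17 and 2 adjusted over the list alone. They included Ccl5 at 27.6-fold and Ccl17 at 22.5-fold (adjusted p = 3.59e-06, and adjusted p = 0.205 with an estimated correlation).

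Interferon-stimulated genes passed as a list in Sirpa-negative cells, with 12 risen and 0 fallen of 33, 15 adjusted over the list alone, led by Gbp2 (38.5-fold) and Ifit1 (6.04-fold; adjusted p = 0.00025, and adjusted p = 0.198 with an estimated correlation). In Sirpa-positive cells 1 of these 33 rose, Gbp2 (4.47-fold), and the list did not pass (adjusted p = 0.293). Type 1 dendritic cell markers had 13 fallen and 2 risen of 27, 19 and 2 adjusted over the list alone (adjusted p = 1.82e-06, and adjusted p = 0.181 with an estimated correlation). Tlr3 and Gcsam (4.16-fold) fell, and the endocytic receptor gene Ly75 (2.97-fold) and Nfil3 (3.52-fold) rose. Type 2 markers went both ways, with 6 risen, among them Irf4 and S100a4 (11.9-fold), and 8 fallen, among them Ccr2 (6.89-fold, 1 of 2 mature arrays), of 30 (8 and 10 adjusted over the list alone), and the list did not pass (adjusted p = 0.342). Cell cycle genes had 22 fallen and 0 risen of 37, 32 fallen adjusted over the list alone, with the replication gene Mcm2 at 3.07-fold and Cdc6 at 4.35-fold (adjusted p = 5.13e-14, and adjusted p = 0.238 with an estimated correlation). The MHC class II list did not pass (adjusted p = 0.485), although the lysosomal protease gene Lgmn rose 9.77-fold and H2-Eb2 9.41-fold. Beside these groups, 19 of 26 thymocyte and T cell markers were higher in the mature samples and 1 lower, 23 and 1 adjusted over the list alone. They were led by Tcf7 (12.3-fold) and Themis (4.70-fold, 1 of 2 immature arrays; adjusted p = 2.6e-11, and adjusted p = 0.0741 with an estimated correlation). Of 28 macrophage and monocyte markers, 5 were higher, among them Axl (29.9-fold), and 2 were lower, a list that did not pass (adjusted p = 0.352).

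In all, 2226 genes rose and 1749 fell with maturation in Sirpa-negative cells (3975 of 24145, 56% of them rises), 1934 and 1291 of them by at least 2-fold. The balance was not stable, with 47.6% rises under median scaling and 49.2% under normexp with quantile normalization. The total was 2305 without immature replicate 7, 2035 without immature replicate 4, 1770 without mature replicate 2, 1615 with dim probes kept and 2043 from these 4 arrays alone. Scaling arrays to their median moved the median change of all genes from 0.03 to -0.07 (Sirpa-positive) and from -0.01 to -0.12 (Sirpa-negative). Over the alternatives the log2 rise lay between 4.83 and 8.61 for Gng4, 5.61 and 7.62 for Ccl22, 4.47 and 6.63 for Insl6, 3.89 and 6.48 for Jag1 and 4.77 and 6.61 for Ccr7. It lay between 2.18 and 3.86 for Irf4, 0.93 and 1.70 for Sirpa and 1.12 and 2.25 for Cd80, of whose 2 kept probes 1 passed singly. Xcr1 passed in 16 of 21 alternatives (adjusted p from 0.000428 to 0.0872), and it missed without mature replicate 2 (0.0872) or 8 (0.067), without immature replicate 4 (0.0835) or 7 (0.071) and with dim probes kept (0.0741). Klk1b26 missed as the mean of its 2 probes, of which 1 passed singly, where its log2 change was -1.50 in place of -3.77 (0.0775, within a range from 0.00023 to 0.0775). Irf8 passed in 5 of 22 alternatives, without Sirpa-positive mature replicate 1 or 6 (log2 change -0.74 in each), with normexp and quantile normalization (adjusted p = 0.0216), the authors' values (0.0466) and trended and robust variances (0.0391). Its change was under the 2-fold minimum.

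**Figure D3:**
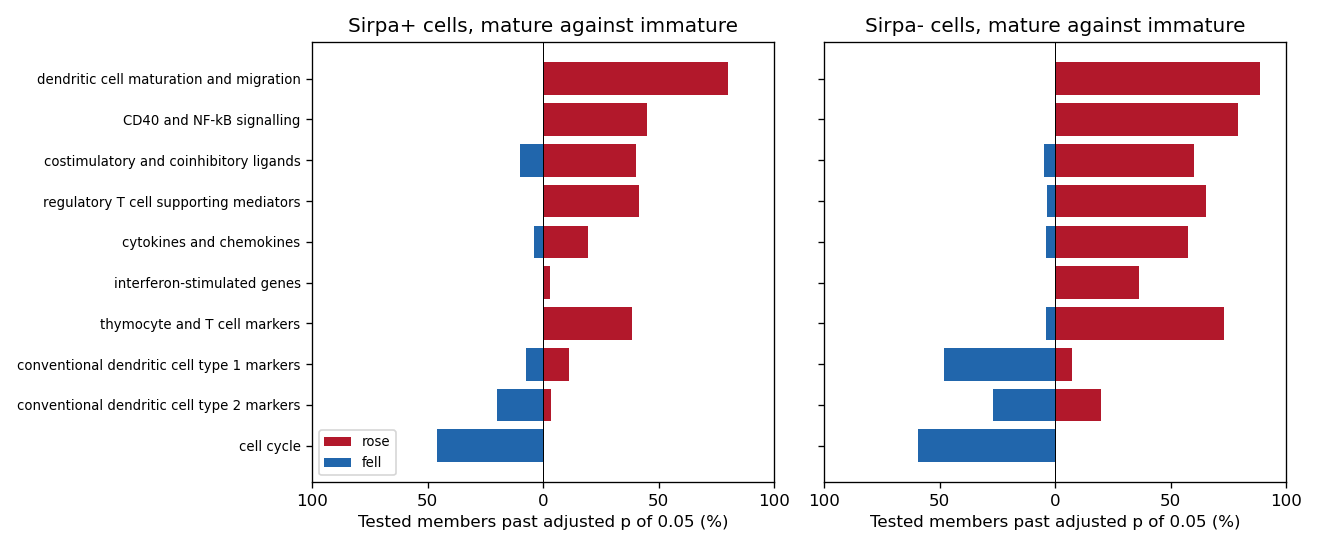
Bars give the percent of each list's tested members that rose (red, to the right) or fell (blue, to the left) with maturation at an adjusted p under 0.05 in Sirpa-positive (left) and Sirpa-negative cells (right). In the maturation and migration list, 28 and 31 of 35 genes rose.

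The maturation changes of the subsets, which share no array, overlapped. Risen in both were 874 genes, against 96.8 for independent lists of these sizes, and fallen in both were 402, against 44.3. Cd40, Ccr7, Cd80, Ccl22, Cd70, Relb and Tcf7 were among the former and Cd209a among the latter. Genes that rose in Sirpa-positive and fell in Sirpa-negative cells numbered 0, and 6 did the opposite. The effects correlated across genes at a Pearson r of 0.672 and a Spearman rho of 0.573, where genes are not independent replicates, and 92.4% of the 4355 genes that passed in at least 1 subset had the same sign in both. The count of 1276 shared genes was 584 without Sirpa-positive mature replicate 1, 345 without mature replicate 6, 360 without immature replicate 3, 342 without immature replicate 5, 827 with the slide row as a block, 840 from the compared arrays alone and 339 with dim probes kept.

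**Figure D4:**
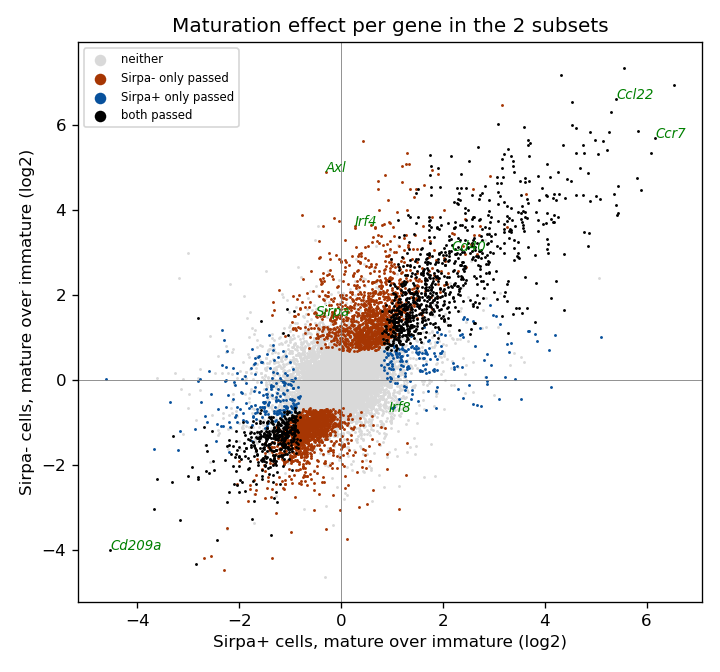
Each point is 1 of 24145 genes, with its log2 change from immature to mature in Sirpa-positive cells (x) and in Sirpa-negative cells (y), coloured by the comparisons in which it passed. Black points passed in both, 1276 with the same sign and 6 more that fell in Sirpa-positive and rose in Sirpa-negative cells.

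Whether maturation changed a gene by a different amount in the subsets was tested directly as the Sirpa-positive change minus the Sirpa-negative change. Irf4 differed by -3.35 ± 0.350 on the log2 scale (SE, n = 2 arrays per group), Sirpa by -2.01 ± 0.316 and Irf8, a transcription factor of type 1 dendritic cells, by 1.68 ± 0.348. Over the alternatives the difference lay between -3.585 and -1.906 for Irf4, -2.194 and -1.558 for Sirpa and 1.286 and 1.994 for Irf8. For these 3 genes the adjusted p over the 8 genes fixed beforehand was 0.000181, 0.00133 and 0.00454, and over all genes it was 0.0688, 0.0929 and 0.153. Cd40 differed by -0.88 ± 0.444 (adjusted p = 0.114 over the 8 genes), Cd80 by -0.66 ± 0.326 (0.114), Cd86 by 0.81 ± 0.305 (0.0642) and Ccr7 by 0.48 ± 0.845 (0.59), and none of these passed. Xcr1 did not pass either (0.242), and the size of its difference is not given because it was below background in Sirpa-positive mature cells. Across all genes limma called 0, with 1945 at an unadjusted p under 0.05 where chance gives 1207, and the lowest adjusted p was 0.0688, shared by 25 genes. That count of 0 was 182 after normexp and quantile normalization, 151 with the authors' values, 101 with probes above background on all 8 arrays, 186 with trended and robust variances, 4 with the mean of probes, 2 with the title-number block, 1 with median scaling and 1 without Sirpa-negative mature replicate 2. Irf4 passed over all genes in 4 of 21 alternatives (adjusted p from 0.00233 to 0.426), Sirpa in 2 (0.00802 to 0.426) and Irf8 in 2 (0.0201 to 0.557).

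Of the fixed lists, 14 passed the test of the difference at the preset correlation and 0 with an estimated one. The MHC class II list passed only with normexp and quantile normalization (camera adjusted p = 0.000313), quantile scaling (0.00373) and the authors' values (0.00068). With normexp the actin (0.0202), cholesterol synthesis (0.0346) and liver X receptor target (0.0303) lists passed too. The authors' values gave such calls for actin (0.0284) and liver X receptor targets (0.0454). Type 1 dendritic cell markers lay higher in the Sirpa-positive change (camera adjusted p = 9.9e-12, and adjusted p = 0.118 with an estimated correlation), and 9 of 27 passed adjusted over the list alone against 0 over all genes. Of this list, Gcsam and Clnk were below background in both Sirpa-positive states and Xcr1 in the mature one. A fall of such members cannot be measured fully there, which may add to the difference. Interferon-stimulated genes lay lower, with 8 of 33 passing adjusted over the list alone (adjusted p = 1.13e-09, and adjusted p = 0.118 with an estimated correlation). So did CD40 and NF-kB signalling, with 0 of 29 passing adjusted over the list alone (adjusted p = 7.74e-07, and adjusted p = 0.142 with an estimated correlation), and costimulatory and coinhibitory ligands, with 5 of 20 (adjusted p = 8.18e-06, and adjusted p = 0.238 with an estimated correlation). Thymocyte and T cell markers lay lower as well, with 0 of 26 passing adjusted over the list alone (adjusted p = 3.44e-05, and adjusted p = 0.118 with an estimated correlation), and macrophage and monocyte markers too, with 4 of 28 lower and 1 higher adjusted over the list alone (adjusted p = 1.62e-07, and adjusted p = 0.248 with an estimated correlation).

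Among immature cells, the subsets differed in many genes at high fold. Complement C1qa was 1060-fold higher in Sirpa-positive cells (10.05 ± 0.378 on the log2 scale, SE, n = 2 arrays per group, adjusted p = 2.37e-05), C1qb 396-fold and C1qc at least 585-fold. Irf4 was 23.9-fold higher (4.58 ± 0.248, adjusted p = 7.2e-05). Xcr1 was 52.3-fold lower (-5.71 ± 0.290, adjusted p = 5.65e-05), Irf8 7.20-fold lower (-2.85 ± 0.246) and Cd86 3.74-fold lower (-1.90 ± 0.215). Cd40 at 0.53 ± 0.314, Ccr7 at -1.17 ± 0.597 and Cd80 at -0.19 ± 0.231 did not pass (adjusted p = 0.356, adjusted p = 0.28 and adjusted p = 0.664).

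Higher in Sirpa-positive immature cells were also the macrophage elastase gene Mmp12 (368-fold), Ms4a7 (at least 269-fold), Gpnmb (at least 176-fold), the ceruloplasmin gene Cp (at least 129-fold) and the lectin Clec4a3 (at least 95.4-fold). Lower were Gpr141b (382-fold) and Gpr33 (78.1-fold), both measured on 1 of the 2 Sirpa-positive arrays, and Gcsam (at least 60-fold), the Wnt receptor gene Fzd1 (at least 47.5-fold), Naalad2 (at least 41.1-fold), Cltrn (at least 39.2-fold), the alkaline phosphatase gene Alpl (at least 32.4-fold) and the adaptor gene Clnk (at least 30.3-fold). Type 1 markers were lower in 23 of 27 and higher in 1, Nfil3 (2.00-fold), with 23 and 1 adjusted over the list alone (camera adjusted p = 1.73e-21, and adjusted p = 0.0868 with an estimated correlation). Of the type 2 markers, 22 of 30 were higher and 0 lower, also adjusted over the list alone, among them Clec4a1 (at least 158-fold; adjusted p = 7.28e-19, and adjusted p = 0.0741 with an estimated correlation). Macrophage and monocyte markers were higher in 25 of 28 and lower in 0, with 26 adjusted over the list alone. Among them were C1qb and the lipid receptor gene Trem2 (at least 77.7-fold; adjusted p = 2.88e-29, and adjusted p = 0.118 with an estimated correlation). The labels name no gate against macrophages. Markers of other cell types were higher too. Granulocyte and mast cell markers were so in 3 of 9 and lower in 0, 6 adjusted over the list alone, among them Prg2 (6.73-fold, 1 of 2 Sirpa-negative arrays; adjusted p = 6.78e-05, and adjusted p = 0.181 with an estimated correlation). Thymic epithelial and stromal markers were higher in 4 of 15 and lower in 0, also adjusted over the list alone, among them Kdr (5.75-fold; adjusted p = 0.000941, and adjusted p = 0.248 with an estimated correlation). Plasmacytoid markers were higher in 8 of 25 and lower in 2, 10 and 6 adjusted over the list alone, among them Lag3 (8.47-fold; adjusted p = 0.0368, and adjusted p = 0.406 with an estimated correlation).

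Receptors and sensors differed too. Endocytic and phagocytic receptors were higher in Sirpa-positive immature cells in 18 of 24 and lower in 3 (18 and 4 adjusted over the list alone). Axl, a receptor for dying cells, stood 174-fold higher and Clec9a, another such receptor, 64.6-fold lower (adjusted p = 4.99e-12, and adjusted p = 0.121 with an estimated correlation). Chemokine and trafficking receptors had 11 higher and 3 lower of 23 (12 and 4 adjusted over the list alone). The fractalkine receptor gene Cx3cr1 was 143-fold and Cmklr1 at least 96.9-fold higher, and Cxcr3 25.9-fold lower (adjusted p = 0.00239, and adjusted p = 0.142 with an estimated correlation). The list call ended when probes had to be above background on all 8 arrays (adjusted p = 0.0666). Of the toll-like receptors and innate sensors, 10 of 30 were higher, led by Tlr1 (17.5-fold), and 3 lower, led by Tlr11 (20.1-fold) and Tlr3 (15.0-fold), or 12 and 4 adjusted over the list alone (adjusted p = 0.00282, and adjusted p = 0.142 with an estimated correlation). Interferon-stimulated genes were higher in 14 of 33 and lower in 0, 19 adjusted over the list alone, led by Ifit3 (55.5-fold) and Rtp4 (53.0-fold; adjusted p = 1.32e-09, and adjusted p = 0.118 with an estimated correlation). Cytokines and chemokines had 11 higher and 2 lower of 26, 12 and 3 adjusted over the list alone, with Ccl9 at 156-fold and Ccl6 at 22.0-fold (adjusted p = 1.73e-06, and adjusted p = 0.198 with an estimated correlation). Liver X receptor targets, genes of cholesterol efflux, were higher in 8 of 17 and lower in 0, 11 adjusted over the list alone, with the lipid carrier gene Apoe at 233-fold and Nr1h3 at 18.9-fold (adjusted p = 7.16e-08, and adjusted p = 0.181 with an estimated correlation). Mediators supporting regulatory T cells were higher in 10 of 29 and lower in 2, 12 and 3 adjusted over the list alone, among them Il2rg (9.78-fold) and Ccl17 (22.5-fold; adjusted p = 0.000431, and adjusted p = 0.34 with an estimated correlation). Costimulatory and coinhibitory ligands were higher in 7 of 20 and lower in 1, 8 and 1 adjusted over the list alone, led by Tnfsf8 (17.1-fold; adjusted p = 0.00154, and adjusted p = 0.368 with an estimated correlation).

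In this comparison 1746 genes were higher and 1061 lower in Sirpa-positive cells (2807 of 24145), 1589 and 866 of them by at least 2-fold. The total was 1666 without Sirpa-positive replicate 5, 1231 without Sirpa-positive replicate 3 and 1557 with dim probes kept. The log2 difference lay between 8.93 and 10.60 for C1qa, 6.87 and 8.68 for Mmp12 and -9.47 and -5.42 for Gpr141b over the alternatives. Ccr7 passed without Sirpa-negative replicate 7 (adjusted p = 0.0408), at a log2 difference of -2.09 (range of adjusted p 0.0408 to 0.808).

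Among mature cells the subsets kept large differences in the same complement genes. C1qa was 385-fold higher in Sirpa-positive cells (8.59 ± 0.378 on the log2 scale, SE, n = 2 arrays per group, adjusted p = 8.66e-05), C1qb 267-fold and C1qc at least 419-fold. Xcr1 was at least 27.8-fold lower. Irf4 was 2.34-fold higher (1.23 ± 0.248, adjusted p = 0.0334), Irf8 2.24-fold lower (-1.16 ± 0.246, adjusted p = 0.0399) and Cd86 2.14-fold lower (-1.10 ± 0.215, adjusted p = 0.03). Cd40 at -0.36 ± 0.314, Ccr7 at -0.70 ± 0.597 and Cd80 at -0.85 ± 0.231 did not pass (adjusted p = 0.707, adjusted p = 0.694 and adjusted p = 0.0929).

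Other genes at the top among mature cells were Mmp12 (279-fold) and Olfml3 (207-fold), both measured on 1 of the 2 Sirpa-negative arrays, Cx3cr1 (at least 226-fold), Gpnmb (at least 102-fold) and Clec4a3 (at least 52.3-fold). Lower were Clec9a (55.1-fold, 1 of 2 Sirpa-positive arrays), Gpr141b (39.9-fold), Cltrn (at least 14.8-fold), the lectin gene Clec1a (at least 12.8-fold), Naalad2 (at least 11.4-fold), Gcsam (at least 10.6-fold) and Clnk (at least 8.31-fold). Type 1 markers were lower in 19 of 27 and higher in 0, 21 adjusted over the list alone, among them Gpr33 (30.5-fold; camera adjusted p = 7.85e-21, and adjusted p = 0.0868 with an estimated correlation). Type 2 markers were higher in 19 of 30 and lower in 0, 21 adjusted over the list alone (adjusted p = 1.14e-22, and adjusted p = 0.0741 with an estimated correlation). Macrophage and monocyte markers were higher in 18 of 28 and lower in 0, 19 adjusted over the list alone, among them Trem2 (at least 43.6-fold; adjusted p = 1.31e-27, and adjusted p = 0.118 with an estimated correlation). Endocytic and phagocytic receptors were higher in 14 of 24 and lower in 3, 17 and 3 adjusted over the list alone. The antibody receptor gene Fcgr3 was 27.6-fold higher and the scavenger receptor gene Cd36 9.42-fold lower on 1 of 2 Sirpa-positive arrays above background (adjusted p = 5.45e-13, and adjusted p = 0.118 with an estimated correlation). Liver X receptor targets were higher in 7 of 17 and lower in 0, 9 adjusted over the list alone, with Apoe at 136-fold and Pltp at 21.7-fold (adjusted p = 1.62e-07, and adjusted p = 0.181 with an estimated correlation). The maturation and migration genes did not differ as a list (adjusted p = 0.215), with Cd86 the only 1 of 35 that passed. Mediators supporting regulatory T cells did not either (adjusted p = 0.387), with 1 higher, Aldh1a2 (at least 17.2-fold), and 2 lower of 29, nor did costimulatory and coinhibitory ligands (adjusted p = 0.743). Plasmacytoid markers were higher in 8 of 25 and lower in 1, 10 and 2 adjusted over the list alone, among them Lair1 (19-fold; adjusted p = 6.07e-06, and adjusted p = 0.18 with an estimated correlation). Thymocyte and T cell markers were lower in Sirpa-positive cells in 3 of 26 and higher in 0, 5 adjusted over the list alone, among them Cd8b1 (3.87-fold) and Rag2 (2.85-fold, 1 of 2 Sirpa-positive arrays; adjusted p = 0.0024, and adjusted p = 0.142 with an estimated correlation).

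Here 815 genes were higher and 507 lower in Sirpa-positive cells (1322 of 24145), 782 and 480 of them by at least 2-fold. The total was 861 without Sirpa-positive replicate 1, 635 without Sirpa-positive replicate 6, 725 without Sirpa-negative replicate 8 and 579 with dim probes kept. Over the alternatives the log2 difference lay between 7.91 and 8.86 for C1qa, 6.19 and 9.41 for Mmp12 and 5.64 and 7.98 for Olfml3. With the slide row as a block the calls of Irf4 (0.0652), Irf8 (0.0698) and Cd86 (0.0645) ended, and so they did with dim probes kept (0.131, 0.151 and 0.126) and from the compared arrays alone (0.0891, 0.132 and 0.118). Array weights ended those of Irf4 (0.057) and Irf8 (0.0613), and median scaling those of Irf8 (0.0655) and Cd86 (0.0559). The calls of the 3 genes were fragile, passing in 13, 10 and 10 of 22 alternatives for Irf4, Irf8 and Cd86, with adjusted p from 0.00106 to 0.148, from 0.000621 to 0.153 and from 0.00283 to 0.126. Irf4 missed without Sirpa-positive mature replicate 1 (0.111) or 6 (0.139), Sirpa-negative mature replicate 8 (0.148) and Sirpa-positive immature replicate 3 (0.062) or 5 (0.0623). Cd86 and Irf8 missed without Sirpa-positive mature replicate 1 (0.117 and 0.126), Sirpa-negative mature replicate 2 (0.122 and 0.125) or 8 (0.103 and 0.153). They missed too without Sirpa-positive immature replicate 3 (0.0678 and 0.0845) or 5 (0.0679 and 0.0847) and Sirpa-negative immature replicate 4 (0.0519 and 0.0634) or 7 (0.052 and 0.0636), and Cd86 without Sirpa-positive mature replicate 6 (0.0507). Cd80 passed in 2 of 22 alternatives, with normexp and quantile normalization (0.0319) and with trended and robust variances (0.0274), and its difference was under the 2-fold minimum.

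The remaining pairs of groups differed in both subset and maturation. Sirpa-positive mature against Sirpa-negative immature cells gave 2654 genes higher and 2321 lower (4975), which was 3210 without Sirpa-positive mature replicate 1 and 2945 with dim probes kept. Sirpa-negative mature against Sirpa-positive immature cells gave 2394 higher and 2176 lower (4570), which was 2577 without Sirpa-positive immature replicate 5, 2399 without Sirpa-positive immature replicate 3 and 2775 with dim probes kept.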

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

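The tests of thymocyte RNA, of Tcf7, of the share of dendritic cells and of Sirpa-positive or mature cells in other samples were chosen after the results were seen; the test of array noise and that of low array readings were chosen before. The genes and lists of the first paragraphs drew attention because their maturation change differed between the subsets by a test of the difference itself, and the patterns after them were seen in counts of calls and in list results. Of the 8 genes fixed beforehand, Irf4 (-3.35), Sirpa (-2.01) and Irf8 (1.68) differed, as the Sirpa-positive minus the Sirpa-negative log2 change, when adjusted over those 8 genes. They did not pass over all 24145 genes.

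Lists differed too, at the preset correlation only, with none (0) passing at an estimated one. The median differences in log2 change, which include members below background, were -0.65 for maturation and migration, -0.67 for costimulatory and coinhibitory ligands, -0.48 for CD40 and NF-kB signalling, -0.58 for cytokines and chemokines, -0.66 for mediators supporting regulatory T cells, -0.45 for interferon-stimulated genes and -0.79 for endocytic and phagocytic receptors. For cell type markers they were 0.89 for type 1 and -0.52 for type 2 dendritic cells, -0.46 for thymocytes and T cells, -0.99 for macrophages and monocytes, -0.31 for thymic epithelium and stroma and -1.91 for granulocytes and mast cells. Ribosomal proteins gave 0.37, a call that ended under quantile scaling, normexp and the authors' values. Some medians differed in size between the first and second row of the slide. They were -1.03 and -0.08 for maturation and migration, -0.99 and -0.06 for thymic epithelium and stroma and 0.08 and 0.65 for ribosomal proteins. Others lay close, such as -0.60 and -0.65 for interferon-stimulated genes.

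More genes changed with maturation in Sirpa-negative than in Sirpa-positive cells, 3975 against 1662, and noisier Sirpa-positive arrays were weighed as a technical candidate. The single model estimates 1 spread per gene over all 8 arrays, so both comparisons had the same SE (for Cd40 0.314 in each). Noise in the arrays of 1 subset would therefore not lower the count of that subset alone. Noisier Sirpa-negative arrays could raise the Sirpa-negative count, because the shared SE would be too small for them. Array weights were lower for Sirpa-negative than for Sirpa-positive arrays in each state (mature 0.774 against 0.866, immature 1.01 against 1.48). From the compared arrays alone the Sirpa-negative count was 2043, while the Sirpa-positive count stayed within 1.5 times of 1662. The covariance of the maturation changes between disjoint pairs of replicates holds no array noise. It was taken over genes well above background on all 8 arrays, so genes dim in any group are not covered. Among them it was 1.84 times as large in Sirpa-negative cells (1.61 to 2.08 over pairings, with and without quantile scaling). Noise alone predicted a ratio of at most 1.2, so for these genes the ratio argues against noise as the whole difference. A larger change in Sirpa-negative cells, or a sort of immature Sirpa-negative cells at an earlier state, may explain it and was not tested apart.

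Genes typical of Sirpa-positive cells rose with maturation in Sirpa-negative cells: 580 genes were both higher in immature Sirpa-positive cells and risen in Sirpa-negative ones, against 161 for independent lists. Unchanged groups simulated 20 times shared 0, which is chance with no effect and does not measure what the shared immature Sirpa-negative arrays add among genes that do change, so part of the excess may come from them. Genes were also picked that lay, on 1 of those arrays, at least 2 on the log2 scale below both immature Sirpa-positive and mature Sirpa-negative cells. Against the other array, 84.8% (of 165 genes) and 87.1% (of 210 genes) still lay 2-fold or more below both. This argues against low readings of a single array as the whole gap of these genes. The second limit was laxer than the pick, so a reading low by up to 2-fold would pass. Genes of the pattern with smaller gaps were not picked. In the 508 that were above background in the other groups, the mature Sirpa-negative level had a median of 70.7% of the mature Sirpa-positive one (quartiles 46.5 and 92.0), while Sirpa stood at 3.54% (upper limit 4.82%), C1qa at 0.26%, Apoe at 0.733%, Lyz2 at 0.767%, Irf4 at 42.7% and Axl at 21.1%, so Sirpa-positive cells in the mature Sirpa-negative samples cannot carry most of it, if such cells hold Sirpa RNA at that gate's mean. A share of mature cells in the immature Sirpa-positive samples would bring at least that share of every mature transcript. It is argued against by the 8 leading risers of Sirpa-positive maturation, Ccr7 (fixed beforehand) among them, which stood there at a median of 2.31% of their mature level (1.40 to 2.44) against 70.2% for the 508 genes. A gain of such genes by maturing Sirpa-negative cells is a hypothesis found and tested on the same arrays. The 508 were picked for rising, so their high percent is partly built in. So is the low percent of the 8 leading risers, which were picked for the size of their rise.

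Thymocyte and T cell markers were higher in mature cells, and 92.3% of the 26 tested members (24) were so in both subsets. RNA from thymocytes would require this, but the share largely restates the list result that raised the question. It therefore cannot tell thymocyte RNA from other causes. The labels name no gate that would remove thymocytes. Tcf7 rose by 1.28 more on the log2 scale than the highest of 20 other members in Sirpa-positive cells and by 1.56 in Sirpa-negative cells. It was singled out because it led the list, and a rise from added RNA depends on each gene's own baseline, so its rise cannot be told apart from thymocyte RNA. Markers of B, NK, granulocyte and erythroid cells (42 genes) had median changes of 0.213 in Sirpa-negative and 0.143 in Sirpa-positive cells, against 1.48 and 0.91 for the thymocyte list, with upper quartiles of 0.697 and 0.626. A lower share of dendritic cells could raise markers of other types, by amounts that depend on which cells make up the rest and on each gene's baseline. Granulocyte and mast cell markers fell in Sirpa-positive cells (median -0.95, camera adjusted p = 0.00447). That call ended with an estimated correlation (adjusted p = 0.259), and most of those genes lay near background. These values therefore cannot decide whether the share of dendritic cells was lower. Expression by mature dendritic cells of some of these genes may contribute and was not tested.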

How the results depend on the processing

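The mean of a gene's probes was an alternative chosen after seeing the data; the rest were fixed beforehand. No call of a named gene or list changed sign. Some values that did not pass did change sign, such as that of Ccr7 in the difference in maturation effect (log2 -0.44 to 1.40). The balance of calls moved too: 47.6% of the calls in Sirpa-negative maturation were rises with median scaling and 49.2% with normexp and quantile normalization, against 56% as reported. No paired analysis was possible because the groups share no replicate number. The slide row and the set of title numbers, which each hold 1 array of every group, were fitted as blocks instead. The difference in maturation effect between subsets, 0 genes as reported, gave 182 with normexp and quantile normalization, 1 with median scaling, 151 with the authors' values, 101 with probes above background on all 8 arrays, 2 with the title-number block, 186 with trended and robust variances and 4 with the mean of probes; the cause was not tested. Keeping dim probes lowered the counts to 430 (Sirpa-positive maturation), 1615 (Sirpa-negative maturation), 1557 (immature subsets), 579 (mature subsets), 2945 and 2775 (the remaining pairs) and 339 (both maturations), in a test over more probes; further causes were not tested. The slide row as a block gave 1061 for Sirpa-positive maturation and 827 for both, and the compared arrays alone, which leave fewer degrees of freedom, 2043 for Sirpa-negative maturation and 840 for both. An estimated correlation left 0 list calls.

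Leaving out each array in turn, with the lone array assumed to vary like the other groups, gave 390 to 1538 for Sirpa-positive maturation, 1770 to 3655 for Sirpa-negative maturation, 1231 to 2768 for immature subsets, 635 to 1266 for mature subsets, 0 to 1 for the difference, 3210 to 5024 and 2399 to 4348 for the remaining pairs and 342 to 1074 for both. Of all counts, 143 stayed within 1.5 times and 39 did not, 44 and 20 of these with an array left out. Named genes kept their side of the threshold in 2106 cases, lost it in 60 and gained it in 24; lists did so in 943, 111 (85 of them with an estimated correlation) and 26. Array weights came out equal for both arrays of a group (0.774 to 1.48), so they weight groups. Deviations of arrays in the same slide row correlated at a median of -0.095 (-0.26 to 0.14) and of those in the same set of title numbers at 0.15 (0.026 to 0.26). Signal near background limits what dim genes can show.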

Other observations

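The list tests in this part were planned, and the ratio of covariances at its end was added once the counts of the subset comparisons had been seen, with its value still unknown. Metabolic and stress lists went different ways. Of 27 ribosomal protein genes 0 changed with maturation in either subset. Between immature subsets the list lay lower in Sirpa-positive cells (median log2 difference -0.52, camera adjusted p = 4.18e-05, and adjusted p = 0.503 with an estimated correlation), with Rpl14 the 1 that passed (1.70-fold lower). Oxidative phosphorylation had 0 of 27 changed in Sirpa-positive maturation (adjusted p = 0.0489, and adjusted p = 0.352 with an estimated correlation, and 0.0552 with probes above background on all 8 arrays) and 1 in Sirpa-negative maturation, Cycs, the cytochrome c gene (1.79-fold lower; camera adjusted p = 0.0225, and adjusted p = 0.303 with an estimated correlation, and 0.0528 with probes above background on all 8 arrays). In glycolysis the muscle enolase gene Eno3 rose 6.49-fold and 13.7-fold in the Sirpa-positive and Sirpa-negative subsets while the glucose transporter gene Slc2a3 fell 3.82-fold and 1.97-fold, in a list with 2 risen and 2 fallen of 23 and 3 risen and 6 fallen (adjusted p = 0.095 and adjusted p = 0.0489). Which subset passed depended on the setting. In Sirpa-positive cells the list passed with normexp and quantile normalization (0.0149), quantile scaling (0.0266), the authors' values (0.0223) and dim probes kept (0.0148). The Sirpa-negative call ended at 0.579 with an estimated correlation, 0.0942 with median scaling, 0.0558 with quantile scaling, 0.0507 with normexp, 0.0623 with the authors' values and 0.098 with probes above background on all 8 arrays. Immediate early and dissociation stress genes did not pass with maturation (adjusted p = 0.293 and adjusted p = 0.168), although Egr1 fell 2.59-fold in Sirpa-negative and Egr3 2.84-fold in Sirpa-positive cells and Dusp2 rose 3.17-fold in the latter. They lay lower in Sirpa-positive cells among immature cells (adjusted p = 0.0225, and adjusted p = 0.446 with an estimated correlation) and among mature cells (adjusted p = 0.0239, and adjusted p = 0.449 with an estimated correlation).

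Apoptosis regulators passed as a list, with 7 risen and 1 fallen of 24 in Sirpa-positive cells (adjusted p = 0.0133, and adjusted p = 0.181 with an estimated correlation) and 11 and 2 in Sirpa-negative cells (adjusted p = 0.0143, and adjusted p = 0.181 with an estimated correlation). The inhibitor gene Cflar rose 4.96-fold in Sirpa-negative cells, and Casp6 fell 3.64-fold and 3.01-fold in the Sirpa-positive and Sirpa-negative subsets. In the actin list the bundling protein gene Fscn1 rose 12.9-fold and 38.9-fold and the tubulin gene Tubb2b 6.07-fold and 10.2-fold, with 6 risen and 0 fallen of 31 and 8 risen and 3 fallen (adjusted p = 0.0387 and adjusted p = 0.0946). The Sirpa-negative list passed with normexp and quantile normalization (0.00638), quantile scaling (0.0246), the authors' values (0.00885) and probes above background on all 8 arrays (0.0387). The Sirpa-positive call ended at 0.621 with an estimated correlation, 0.0742 with normexp, 0.101 with quantile scaling, 0.0808 with the authors' values and 0.077 with dim probes kept. Aire, the transcriptional regulator best known from thymic epithelium, rose 4.88-fold in Sirpa-positive and 7.26-fold in Sirpa-negative cells. The epithelial and stromal list as a whole had 1 risen and 2 fallen of 15 in Sirpa-positive cells (adjusted p = 0.168) and 3 risen in Sirpa-negative cells, among them Kdr (7.70-fold) and Krt5 (3.27-fold; adjusted p = 0.00836, and adjusted p = 0.34 with an estimated correlation). Plasmacytoid markers went both ways, with Bcl11a down 7-fold in Sirpa-positive and 5.06-fold in Sirpa-negative cells (1 of 2 mature arrays above background) and Spib up 2.7-fold and 4.69-fold (adjusted p = 0.258 and adjusted p = 0.137). B cell markers had 3 risen and 1 fallen of 14 in Sirpa-positive maturation (adjusted p = 0.0433, and adjusted p = 0.472 with an estimated correlation, 0.0524 with dim probes kept and 0.269 with probes above background on all 8 arrays) and 4 risen in Sirpa-negative maturation (adjusted p = 0.258), among them Blnk (3.17-fold). NK cell markers did not pass in either (adjusted p = 0.725 and adjusted p = 0.978), with Cd7 down 4.19-fold in Sirpa-positive cells, nor did erythroid markers (adjusted p = 0.725 and adjusted p = 0.484), with the carbonic anhydrase gene Car2 up 6.76-fold and 7.33-fold. Granulocyte and mast cell markers had 1 fallen of 9 in Sirpa-positive cells, Ltf (at least 2.52-fold; adjusted p = 0.00447, and adjusted p = 0.259 with an estimated correlation). The transcription factor and growth factor receptor list did not pass with maturation (adjusted p = 0.611 and adjusted p = 0.506), with Irf1 up 3.76-fold and 7.19-fold and Mycl down 2.31-fold and 3.1-fold.

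The covariance of the subset differences between disjoint pairs of replicates was taken over genes well above background on all 8 arrays. It was 2.33 times as large among immature as among mature cells (1.93 to 2.67 over pairings, with and without quantile scaling).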
